A study of Mus musculus with 15 samples.

How the data were processed

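RNA was extracted with Trizol from primary astrocytes of CD-1 pups, and libraries were made from poly(A) RNA with the Illumina TruSeq mRNA kit, per the labels. Reads were processed with STAR 2.7.3a and featureCounts 2.0.3 (Subread) on GRCm38.p6, per the submitters' processing notes. Read pairs were counted per gene with strand setting 2 and with overlapping features allowed, on an Ensembl-style GRCm38 annotation, per the file headers. Overlapping genes on the same strand can therefore share reads. Trimming, other alignment settings and the filters on reads are not given in the sources used here. The authors then compared each isoform with GFP using DESeq2, per the submitters' processing notes, with no version or design stated.

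The count table lists 51912 genes and 15 columns of counts per the file headers, named by run codes that match no sample label. None of the 15 columns was used, because a column's group would have had to be guessed. The counts were therefore not normalized, filtered or tested here, and the depth of each library, values per library and the check of replicates against each other are not given. The planned test on counts was replaced by the authors' deposited comparisons. The precision of each value is that of the authors' standard error.

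The 4 deposited tables hold, per gene, the base mean, a normalized signal that is the mean of the authors' size-factor normalized counts. They also hold the authors' log2 fold change with its standard error. The remaining columns are the authors' Wald statistic, a score with no fixed range, and the authors' p-value and adjusted p-value. Each holds 21109 lines, 90 of which repeat an identifier and were left out, leaving 21019 genes, 21016 with a GC content from the reference. The base means were the same in all 4 tables, and dispersions rebuilt from the deposited values differed between tables by a median ratio of 1.01 over 10290 genes with a base mean of at least 500, both properties of a single fit over all groups. No standard error exceeded 0.466, and the deposited score differed from fold change over error by a median of 0.00123, 8.9e-04, 0.00114 and 0.00114 and by up to 7.36, 1.18, 4.46 and 5.82 (PGC-1α1 to PGC-1α4). The values nearly coincided for most genes. A Wald statistic is that ratio where values are not shrunken, so the differences argue against unshrunken fold changes. So does a largest error of 0.466 with base means down to 0.629. The sources used here do not state a shrinkage. Adjusted p-values were empty for 1289, 3188, 1539 and 1539 genes in the deposited tables, which stayed untested.

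Genes were called at the authors' adjusted p under 0.05. Isoforms were compared by the difference of deposited fold changes over the square root of the summed squared errors, with Benjamini-Hochberg adjustment over the 17831 genes with an adjusted p in all 4 tables. The errors share the GFP libraries, so this test would be conservative for unshrunken fold changes, and an alternative rebuilt that covariance. On simulated data for the differences between isoforms over 17831 genes, with 200 changed and 5 draws, the summed errors gave 0.556% of unchanged genes a p under 0.05 and called 64.4% of 1.5-fold and 91.2% of 2-fold changes. Taking out the GFP covariance gave 4.99%, 83.6% and 99% in the same simulation. There the covariance came from known dispersions and was not rebuilt from deposited values. The simulation therefore does not check the rebuilding used on the real data. It also used unshrunken fold changes, while the deposited ones appear to be shrunken. Its shares may therefore not hold for differences of the deposited values.

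The 29 gene lists, covering energy metabolism, stress, inflammation, astrocyte states, secreted factors and markers of other cell types, were tested with camera on the Wald statistic (limma 3.58.1 in R 4.3.3, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 29 lists of each comparison. An inter-gene correlation could not be estimated without values per library, so preset values of 0.05 and 0.1 were tried. On simulated lists over 17831 genes, 3.17% of 1450 with no effect had an unadjusted camera p under 0.05. Of 250 shifted by 1.5 statistic units, 99.6% were called after adjustment. Simulated genes were independent, with a spread not matched to the data, so the shares do not cover real lists. Siglech (microglia), Cldn5 and Emcn (endothelial) were on the lists but are not analysed here. Correlations of fold changes used genes with a base mean of at least 50, a filter chosen after the data were seen, without Ppargc1a. Shared-control values came from 20 simulated draws of unchanged groups. GC content and length came from GENCODE M21 (GRCm38), and their trend was taken out over 20 bins fitted on 14204 genes.

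Genes were named by a rule. It took Ppargc1a, Ppargc1b and Pprc1, and up to 3 called members per direction of each list. It also took the 8 highest and 8 lowest called fold changes against GFP (4 and 4 between isoforms) with at least 5 CPM of the summed base means in the higher group, clone and pseudogene names left out. Group means for that minimum were rebuilt from the deposited values, and the planned condition that every isoform library lie on the same side of every GFP library could not be checked. Some genes that the rule picks are not reported here. A gene named for an isoform under which the rule does not pick it was taken from the rule's genes under another isoform. Coordinates are 1-based on GRCm38, from the count table's annotation. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives were Benjamini-Hochberg adjustment over all genes, an adjusted p under 0.01, a base mean of at least 10, median-centred fold changes, the rebuilt covariance, other inter-gene correlations, ranks, fold changes in place of the statistic, and the GC and length correction.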

Results

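Poly(A) RNA was sequenced from 15 libraries of primary mouse astrocytes, cultured from newborn CD-1 pups and infected with adenovirus at a multiplicity of infection of 100 for 24 h. The 5 groups held 3 libraries each. The control virus carried green fluorescent protein (GFP). The other viruses carried 4 isoforms of the transcriptional coactivator PGC-1α, named PGC-1α1, PGC-1α2, PGC-1α3 and PGC-1α4. All isoforms come from the Ppargc1a gene, and PGC-1α1 is the form best known as a driver of mitochondrial gene expression. The series asks how astrocytes respond to each isoform, with PGC-1α2 and PGC-1α3 named in its title. Values are log2 fold changes ± standard error and adjusted p-values, from the authors' deposited table for each isoform against GFP. The depth of each library is not given, because the columns of the count table could not be tied to samples. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The gene lists, the rule for naming genes and the adjusted p threshold of 0.05 were chosen before the data were examined. "Called" means an adjusted p under that threshold, and "up" and "down" are relative to GFP unless another isoform is named. Lists were tested with camera, and BH stands for Benjamini-Hochberg adjustment. List medians are log2 fold changes.

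Ppargc1a itself (ENSMUSG00000029167, GRCm38 chromosome 5, 51454250 to 51567726, minus strand) was the gene with the largest increase under every isoform. The authors' deposited table gave 12.60 ± 0.10 under PGC-1α1, 13.25 ± 0.10 under PGC-1α2, 11.80 ± 0.10 under PGC-1α3 and 12.13 ± 0.10 under PGC-1α4, each with the authors' adjusted p listed as 0. Group means rebuilt from that table put Ppargc1a at 9.06%, 15.4%, 6.63% and 8.35% of the summed normalized counts, in the same order, against 0.00179% under GFP. The level was higher under PGC-1α2 than under PGC-1α1 by 0.66 ± 0.13 (adjusted p 7.5e-06, Wald test of the difference with Benjamini-Hochberg adjustment). It was lower under PGC-1α3 than under PGC-1α2, with a difference of −1.45 ± 0.13 (adjusted p 9.61e-25, the same test and adjustment). Counts per gene cannot tell the isoforms apart. They also depend on the length of the transcript that each virus carried, which is not given here. These levels therefore do not rank the isoforms by number of mRNA molecules. Of the related coactivators, Pprc1 fell under all 4 isoforms (−1.05, −0.66, −0.53 and −0.73 in the authors' deposited table). Ppargc1b was not called under any, with −0.67, −0.33, 0.02 and −0.13 in the authors' deposited table.

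Comparing each isoform with GFP, 11325 genes were called under PGC-1α1, of 19730 tested (5526 up, 5799 down). PGC-1α2 gave 7731 of 17831 (4069 up, 3662 down). PGC-1α3 gave 10352 of 19480 (5188 up, 5164 down) and PGC-1α4 gave 10405 of 19480 (5459 up, 4946 down). The sizes differed more than the counts. A change of at least 1 on the log2 scale was seen for 3237 called genes under PGC-1α1 (1807 up, 1430 down) and 526 under PGC-1α2 (58 up, 468 down). It was seen for 2259 under PGC-1α3 (799 up, 1460 down) and 2427 under PGC-1α4 (729 up, 1698 down). The median absolute log2 fold change of the called genes was 0.67, 0.42, 0.58 and 0.59, in the order PGC-1α1 to PGC-1α4. All these calls use the authors' adjusted p. Their fold changes appear to be shrunken towards 0, which would understate the change of genes with few counts. The standard errors, rebuilt group means and differences between isoforms rest on the same values.

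**Figure D1:**
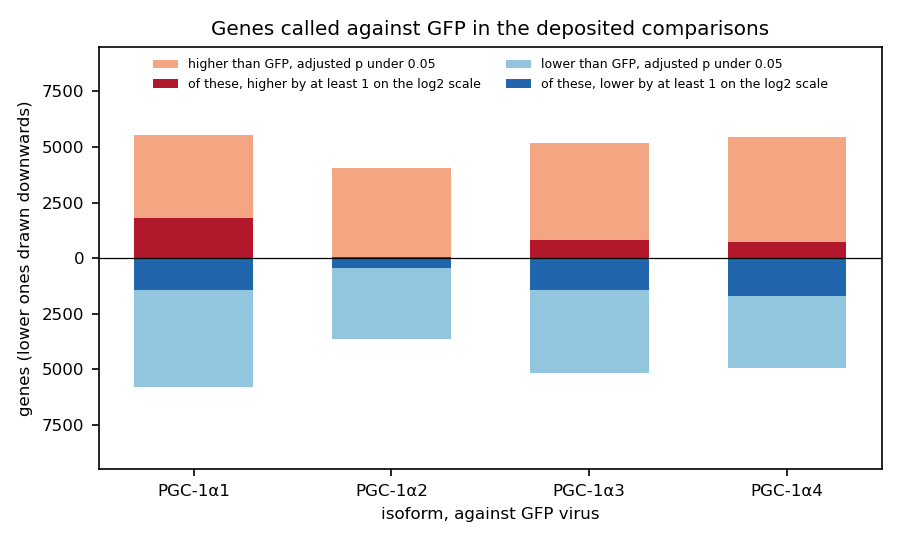
Genes called against GFP under each isoform (bars above 0, higher than GFP; bars below 0, lower; number of genes on the y axis), with the dark part showing changes of at least 1 on the log2 scale. The dark part holds 526 genes under PGC-1α2 and 3237 under PGC-1α1.

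Under PGC-1α1, genes of mitochondrial energy metabolism rose together. All 76 nuclear-encoded subunits of oxidative phosphorylation were called up, and 76 adjusted over the list alone (median 2.09, camera BH-adjusted p 5.49e-46). Among them, the authors' deposited table gave Ndufs1 (2.25 ± 0.047), Sdha (2.19 ± 0.048) and Atp5b (2.44 ± 0.068). All 22 tricarboxylic acid (TCA) cycle genes were called up, and 22 adjusted over the list alone (median 2.16, camera BH-adjusted p 6.44e-80). Examples in the authors' deposited table were Idh3a (3.41 ± 0.056) and Cs (2.58 ± 0.036). Fatty acid oxidation (median 2.02, camera BH-adjusted p 1.07e-36) rose, with 28 of 34 genes up and 2 down. Nothing in these counts changed when adjusted over the list alone. Its members Etfdh (2.58 ± 0.054), Hadhb (2.42 ± 0.052) and Hadha (2.02 ± 0.038) rose in the authors' deposited table. Mitochondrially encoded mRNAs (median 0.69, camera BH-adjusted p 1.31e-04), biogenesis regulators (median 0.96, camera BH-adjusted p 3.31e-08) and glycolysis (median 1.40, camera BH-adjusted p 5.63e-17) also rose. Mitochondrially encoded mRNAs had 10 up and 0 down of 13 genes, biogenesis regulators 16 and 5 of 26, and glycolysis 15 and 3 of 21. P-values adjusted over the list alone gave 11 and 0, 17 and 6, and 15 and 3. Esrra, a nuclear receptor gene that works with PGC-1α, stood at 2.94 ± 0.084, and the mitochondrial deacetylase gene Sirt3 at 2.79 ± 0.065, in the authors' deposited table. For glycolysis, the authors' deposited table gave Hk1 (2.33 ± 0.048) and Pgam1 (2.08 ± 0.054).

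The largest increases after Ppargc1a under PGC-1α1 included Cplx1 (7.43 ± 0.22), Akain1 (7.39 ± 0.35) and Atp2b2 (7.09 ± 0.20) in the authors' deposited table. Cplx1, a synaptic vesicle protein gene, lies on GRCm38 chromosome 5, 108518554 to 108550024, minus strand. Further increases in the authors' deposited table were Tesc (6.85 ± 0.20), Cd164l2 (6.56 ± 0.28), H2-Eb1 (6.48 ± 0.22), Fndc5 (4.78 ± 0.13) and Cox7a1 (5.44 ± 0.19). The neuron marker list as a whole was not called (median −0.37, camera BH-adjusted p 0.578), and its mean of 0.17 differed in sign from its median. It had 7 of 20 genes up and 9 down. Tests adjusted over the list alone called 8 and 9. Of its members, Tubb3 (2.91 ± 0.12), Elavl3 (2.56 ± 0.12) and Nefl (2.30 ± 0.16) rose and Celf4 (−1.32 ± 0.11), Meg3 (−0.91 ± 0.10) and Nefm (−0.58 ± 0.083) fell in the authors' deposited table.

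Stress and inflammatory genes fell under PGC-1α1. Heat shock genes (median −1.0, camera BH-adjusted p 5.53e-12) and inflammatory genes (median −0.66, camera BH-adjusted p 1.54e-05) fell. Heat shock genes had 3 up and 15 down of 19 genes, and inflammatory genes 2 and 26 of 34. The counts adjusted over the list alone were equal. Beside the inflammatory genes, microglia markers had 0 of 21 genes up and 11 down, or 0 and 13 adjusted over the list alone. That list was not called (median −0.36, camera BH-adjusted p 0.0938), but it was with ranks (camera BH-adjusted p = 0.00757) and after correction for GC content and gene length (camera BH-adjusted p = 0.0316). The decreases in the authors' deposited table included Hspa1b (−3.66 ± 0.13), Hspa1a (−3.49 ± 0.14), Hsph1 (−1.93 ± 0.059), Il11 (−2.75 ± 0.15) and Ptgs2 (−2.71 ± 0.11). Hspa1a and Hspa1b are near-identical copies, so the division of reads between them is uncertain. ER stress (median −0.45, camera BH-adjusted p 9.76e-05), p53 targets (median −0.50, camera BH-adjusted p 3.62e-08) and A2-type reactive genes (median −0.87, camera BH-adjusted p 0.00108) fell as well. ER stress had 6 up and 26 down of 40 genes, p53 targets 6 and 23 of 34, and A2-type reactive genes 0 and 8 of 12. The result was 6 and 26, 6 and 23, and 0 and 9 when adjusted over the list alone. Other large decreases in the authors' deposited table were Krt19 (−3.30 ± 0.18), Cdh4 (−3.22 ± 0.17), Nyx (−3.13 ± 0.17), Trank1 (−3.06 ± 0.22), Ereg (−3.05 ± 0.12) and Fosl1 (−3.03 ± 0.11). Genes of the cell cycle (median −0.46, camera BH-adjusted p 0.0122) fell, while those of astrocyte identity (median 0.26, camera BH-adjusted p 0.00576) and lipid synthesis (median 0.31, camera BH-adjusted p 0.0358) rose. The cell cycle had 6 up and 28 down of 40 genes, astrocyte identity 23 and 5 of 40, and lipid synthesis 13 and 8 of 25. Adjusted over the list alone, they were 6 and 29, 24 and 5, and 15 and 8. These last 3 calls were lost at a preset inter-gene correlation of 0.05, with camera BH-adjusted p = 0.126 for the cell cycle, 0.0871 for astrocyte identity and 0.153 for lipid synthesis. The ER stress call was lost at 0.1 (camera BH-adjusted p = 0.0691). The cell cycle call was also lost with fold changes in place of the statistic (camera BH-adjusted p = 0.0613) and that of lipid synthesis with ranks (camera BH-adjusted p = 0.107). Among astrocyte genes, Ndrg2 (3.37 ± 0.085), Acsl6 (1.92 ± 0.073) and Gfap (0.89 ± 0.08) rose and Gja1, which encodes connexin 43, fell (−1.60 ± 0.067) in the authors' deposited table.

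The remaining lists were not called under PGC-1α1. Among them were extracellular matrix (median −0.43, camera BH-adjusted p 0.073) and cholesterol synthesis (median 0.26, camera BH-adjusted p 0.0902). Others were antioxidant defence (median 0.18, camera BH-adjusted p 0.175) and MHC class I (median 0.33, camera BH-adjusted p 0.396). With ranks, some were called, with camera BH-adjusted p = 0.0029 for lower extracellular matrix (5 up and 22 down of 36), 0.00649 for higher cholesterol synthesis (15 up and 1 down of 25) and 0.0234 for higher MHC class I (12 up and 2 down of 22). Extracellular matrix was also called with fold changes in place of the statistic (camera BH-adjusted p = 0.0401). Median, mean and test differed in sign for antioxidant defence (mean −0.05, test down) and the interferon response (median 0.10, mean 0.08, test down). They also differed for fibroblast (median 0.05, mean −0.02, test down) and ependymal markers (median −0.01, mean 0.04, test down).

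Under PGC-1α2, heat shock genes fell, and most changes of at least 1 on the log2 scale were decreases (468 of 526 genes). Heat shock genes (median −0.83, camera BH-adjusted p 6.31e-42) fell, with 0 of 19 genes up and 17 down. Identical counts resulted when adjusted over the list alone. Decreases in the authors' deposited table were Hspa1b (−2.50 ± 0.13), Hspa1a (−2.40 ± 0.14), Hsph1 (−1.67 ± 0.058), Dnajb4 (−1.37 ± 0.046) and Hspb1 (−1.59 ± 0.13), with Hspa1a and Hspa1b uncertain as near-identical copies. The cytokine gene Il11 (−2.18 ± 0.15) fell in the authors' deposited table, as did Ppp1r16b (−1.91 ± 0.16), Trank1 (−1.79 ± 0.21), Ppp1r3g (−1.69 ± 0.29) and Ereg (−1.65 ± 0.11). Increases reached 1 on the log2 scale for 58 called genes. Beside Ppargc1a, the largest in the authors' deposited table included Elobl (1.68 ± 0.18), Abhd14b (1.09 ± 0.10), Hrct1 (1.06 ± 0.20), Rln1 (1.04 ± 0.17) and Urod (1.00 ± 0.10). Elobl lies on GRCm38 chromosome 11, 88964658 to 88966931, minus strand.

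Lists of mitochondrial energy metabolism rose under PGC-1α2 by small amounts, while biogenesis regulators were not called (median −0.25, camera BH-adjusted p 0.223). Those regulators had 5 up and 11 down of 26 genes, the same as adjusted over the list alone. Oxidative phosphorylation (median 0.38, camera BH-adjusted p 1.35e-07), the TCA cycle (median 0.26, camera BH-adjusted p 8.24e-04) and fatty acid oxidation (median 0.31, camera BH-adjusted p 7.72e-05) rose. Oxidative phosphorylation had 59 up and 0 down of 76 genes, the TCA cycle 15 and 1 of 22, and fatty acid oxidation 24 and 2 of 34. These were 66 and 0, 15 and 1, and 24 and 2 when adjusted over the list alone. Examples from the authors' deposited table were Ndufs8 (0.67 ± 0.13), Idh2 (0.69 ± 0.10), Acad11 (0.49 ± 0.055) and Hadha (0.36 ± 0.039), while Esrra was not called (0.08 ± 0.086). The cell cycle (median 0.35, camera BH-adjusted p 8.8e-05) and cholesterol synthesis (median 0.28, camera BH-adjusted p 1.49e-04) rose. The cell cycle had 24 up and 2 down of 40 genes, and cholesterol synthesis 18 and 0 of 25. Counts adjusted over the list alone were 27 and 2, and 19 and 0. The authors' deposited table gave Ccne1 (0.76 ± 0.10), Mcm5 (0.53 ± 0.079) and Nsdhl (0.44 ± 0.062). ER stress (median −0.29, camera BH-adjusted p 9.92e-11), p53 targets (median −0.34, camera BH-adjusted p 2.02e-13) and inflammatory genes (median −0.24, camera BH-adjusted p 0.00149) fell. ER stress had 2 up and 23 down of 40 genes, p53 targets 5 and 21 of 34, and inflammatory genes 2 and 17 of 34. With p-values adjusted over the list alone, the counts were 3 and 24, 5 and 22, and 2 and 18. Among these, Atf3 (−1.33 ± 0.084), Ppp1r15a (−1.15 ± 0.077), Plk2 (−1.46 ± 0.069) and Mdm2 (−1.14 ± 0.048) were lower in the authors' deposited table. Beside the inflammatory genes, microglia markers (median −0.54, camera BH-adjusted p 0.00184) fell, with 0 of 20 genes up and 14 down. Nothing in these counts changed when adjusted over the list alone. Microglial examples from the authors' deposited table were Cx3cr1 (−1.06 ± 0.15), Itgam (−0.78 ± 0.18) and Ptprc (−0.71 ± 0.15).

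Under PGC-1α2, astrocyte identity (median 0.18, camera BH-adjusted p 0.00696) and mitochondrially encoded mRNAs (median 0.16, camera BH-adjusted p 0.0336) rose too. Astrocyte identity had 20 up and 3 down of 39 genes, and mitochondrially encoded mRNAs 5 and 0 of 13. When adjusted over the list alone, they became 21 and 3, and 5 and 0. A2-type reactive genes (median −0.23, camera BH-adjusted p 0.0283) and neuron markers (median −0.26, camera BH-adjusted p 0.0254) fell. A2-type reactive genes had 0 up and 5 down of 11 genes, and neuron markers 3 and 8 of 19. The counts adjusted over the list alone were equal. For antioxidant defence the test pointed down (median 0.08, camera BH-adjusted p 0.00445), as did its mean (−0.14), but its median was above 0 and its genes split about evenly. It had 9 up and 10 down of 31 genes, or 10 and 10 adjusted over the list alone. Its call was lost with ranks (camera BH-adjusted p = 0.557) and with fold changes in place of the statistic (camera BH-adjusted p = 0.296). The antioxidant genes Gclm (−1.32 ± 0.069), Srxn1 (−1.21 ± 0.07) and Txnrd1 (−1.17 ± 0.074) fell in the authors' deposited table. These 5 calls were lost at an inter-gene correlation of 0.05, with camera BH-adjusted p = 0.0885 for astrocyte identity, 0.09 for mitochondrially encoded mRNAs, 0.0839 for A2-type reactive genes, 0.09 for neuron markers and 0.0619 for antioxidant defence. At 0.1 the camera BH-adjusted p was 0.0728 for oxidative phosphorylation, 0.081 for the TCA cycle, 0.0743 for fatty acid oxidation and 0.149 for inflammatory genes. It was 0.081 for the cell cycle, 0.0728 for cholesterol synthesis and 0.092 for microglia markers, so these calls were lost there as well. After correction for GC content and gene length, the camera BH-adjusted p was 0.149 for mitochondrially encoded mRNAs and 0.0521 for neuron markers. Calls lost with ranks had camera BH-adjusted p = 0.0624 for mitochondrially encoded mRNAs, 0.101 for A2-type reactive genes and 0.0678 for neuron markers, and those lost with fold changes had camera BH-adjusted p = 0.322 for mitochondrially encoded mRNAs and 0.124 for A2-type reactive genes. The growth factor list was not called, and its median (0.09) and mean (−0.01) differed in sign.

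Under PGC-1α3, antioxidant, heat shock and inflammatory genes fell. Antioxidant defence (median −0.66, camera BH-adjusted p 4.01e-22), heat shock genes (median −1.10, camera BH-adjusted p 2.01e-32) and inflammatory genes (median −1.35, camera BH-adjusted p 3.14e-21) fell. Antioxidant defence had 5 up and 19 down of 31 genes, heat shock genes 1 and 17 of 19, and inflammatory genes 4 and 26 of 34. Identical counts resulted when adjusted over the list alone. For antioxidant enzymes, the authors' deposited table gave Srxn1 (−3.71 ± 0.071), Nqo1 (−3.49 ± 0.11), Gclm (−3.04 ± 0.07) and Txnrd1 (−2.64 ± 0.074). Slc7a11, the cystine transporter gene on GRCm38 chromosome 3, 49892526 to 50443614, minus strand, stood at −3.99 ± 0.14 in the authors' deposited table. Nos2, the inducible nitric oxide synthase gene on chromosome 11, 78920787 to 78960254, plus strand, stood at −4.40 ± 0.14 in the authors' deposited table. Cytokine genes were lower, with Cxcl5 (−3.49 ± 0.13), Il1a (−3.44 ± 0.12), Il1b (−3.31 ± 0.17) and Il11 (−3.69 ± 0.16) in the authors' deposited table. Heat shock examples in the authors' deposited table were Hspa1a (−4.73 ± 0.14), Hspa1b (−4.65 ± 0.13) and Hsph1 (−2.04 ± 0.059), the Hspa1 pair being uncertain as near-identical copies. Beside the inflammatory genes, microglia markers (median −0.63, camera BH-adjusted p 0.00604) fell, with 1 of 21 genes up and 15 down. Nothing in these counts changed when adjusted over the list alone. Microglial genes Fcer1g (−1.31 ± 0.15), Ptprc (−1.20 ± 0.16) and C1qb (−1.13 ± 0.16) fell in the authors' deposited table, while Trem2 rose (0.50 ± 0.13).

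The largest increases after Ppargc1a under PGC-1α3 included histone genes, with H4c12 (3.07 ± 0.16) and H4c11 (2.91 ± 0.14) in the authors' deposited table. H4c12 (chromosome 13, 21750194 to 21750505, minus strand) and H4c11 (chromosome 13, 21735064 to 21735837, plus strand, GRCm38) belong to a family with near-identical coding sequences, so both values are uncertain. Others in the authors' deposited table were Elobl (2.99 ± 0.18), Glrp1 (2.80 ± 0.14), Nrgn (2.62 ± 0.18), Slco1c1 (2.44 ± 0.087) and Hepacam2 (2.43 ± 0.19). The cell cycle (median 0.44, camera BH-adjusted p 1.05e-04) rose, with 28 of 40 genes up and 3 down. They came to 29 and 3 adjusted over the list alone. Cell cycle genes in the authors' deposited table were Mcm5 (1.01 ± 0.078), Ccne1 (0.98 ± 0.10), Mcm2 (0.87 ± 0.072) and Mcm3 (0.86 ± 0.075). Oxidative phosphorylation (median 0.38, camera BH-adjusted p 1.06e-04) and the TCA cycle (median 0.41, camera BH-adjusted p 7.43e-04) rose. Oxidative phosphorylation had 48 up and 0 down of 76 genes, and the TCA cycle 15 and 2 of 22. The counts were 51 and 0, and 15 and 2 adjusted over the list alone. Fatty acid oxidation (median 0.31, camera BH-adjusted p 0.00126) and cholesterol synthesis (median 0.33, camera BH-adjusted p 0.00447) rose. Fatty acid oxidation had 19 up and 6 down of 34 genes, and cholesterol synthesis 16 and 2 of 25. P-values adjusted over the list alone gave 19 and 6, and 17 and 2. Of these groups and of mitochondrial regulators, the authors' deposited table listed Ndufs8 (1.00 ± 0.13), Idh2 (0.92 ± 0.10), Etfdh (0.96 ± 0.054) and Sirt3 (1.14 ± 0.067). Esrra was not called (−0.08 ± 0.086 in the authors' deposited table).

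Other stress lists fell under PGC-1α3. ER stress (median −0.54, camera BH-adjusted p 9.01e-09) and p53 targets (median −0.55, camera BH-adjusted p 4.4e-12) fell. ER stress had 3 up and 30 down of 40 genes, and p53 targets 6 and 21 of 34. Tests adjusted over the list alone called 3 and 30, and 6 and 24. Pan-reactive genes (median −0.47, camera BH-adjusted p 0.00275) and A2-type reactive genes (median −0.79, camera BH-adjusted p 1.06e-04) fell. Pan-reactive genes had 2 up and 10 down of 13 genes, and A2-type reactive genes 1 and 10 of 12. The counts adjusted over the list alone were equal. Gfap, an intermediate filament gene of the pan-reactive list, rose (1.15 ± 0.08 in the authors' deposited table). Extracellular matrix (median −0.55, camera BH-adjusted p 2.51e-04) and growth factors (median −0.22, camera BH-adjusted p 0.0103) fell. Extracellular matrix had 5 up and 24 down of 36 genes, and growth factors 8 and 14 of 27. The result was 5 and 25, and 9 and 14 when adjusted over the list alone. Lower secreted factors in the authors' deposited table were Mmp3 (−2.64 ± 0.15), Mmp9 (−2.53 ± 0.13), Gdnf (−2.84 ± 0.14) and Vegfa (−1.24 ± 0.06). Of other cell types, oligodendrocyte markers (median −0.34, camera BH-adjusted p 0.00754) and neuron markers (median −0.52, camera BH-adjusted p 0.0103) fell and ependymal markers (median 0.88, camera BH-adjusted p 0.0103) rose. Oligodendrocyte markers had 0 up and 7 down of 18 genes, neuron markers 3 and 10 of 20, and ependymal markers 10 and 0 of 14. Adjusted over the list alone, they were 0 and 7, 3 and 12, and 10 and 0. Named members in the authors' deposited table were Bcas1 (−2.71 ± 0.084) and Nefm (−2.36 ± 0.088) down and Rsph4a (1.63 ± 0.17) and Rsph1 (1.15 ± 0.15) up.

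Some of these calls depended on the preset correlation. Under PGC-1α3 and a correlation of 0.05, the camera BH-adjusted p was 0.0701 for growth factors and 0.0538 for neuron markers, which lost these calls. The growth factor call was also lost with ranks (camera BH-adjusted p = 0.0828) and with fold changes (0.12), as was that of cholesterol synthesis with fold changes (0.051). At 0.1 it was also above the threshold, with camera BH-adjusted p = 0.111 for oxidative phosphorylation, 0.076 for the TCA cycle, 0.111 for fatty acid oxidation and 0.076 for pan-reactive genes. Likewise lost at 0.1 were others, with camera BH-adjusted p = 0.076 for the cell cycle, 0.112 for cholesterol synthesis and 0.088 for extracellular matrix, and 0.111 each for microglia, oligodendrocyte and ependymal markers. Median and mean differed in sign for lists that were not called. These were mitochondrial biogenesis (median −0.05, mean 0.02, test up), autophagy (median 0.06, mean −0.02, test down) and fibroblast markers (median −0.24, mean 0.02, test up).

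Under PGC-1α4, inflammatory and interferon genes fell. Inflammatory genes (median −2.11, camera BH-adjusted p 2.73e-42) and the interferon response (median −0.83, camera BH-adjusted p 3.94e-10) fell. Inflammatory genes had 1 up and 30 down of 34 genes, and the interferon response 1 and 35 of 42. These were 2 and 30, and 1 and 36 when adjusted over the list alone. Inflammatory genes in the authors' deposited table were Nos2 (−5.14 ± 0.16), Cxcl5 (−4.57 ± 0.13), Il1b (−4.28 ± 0.17), Il1a (−3.94 ± 0.12) and Ptgs2 (−3.34 ± 0.11). Interferon-induced genes in the authors' deposited table were Mx1 (−2.94 ± 0.17), Gbp5 (−2.35 ± 0.14) and Cxcl10 (−2.30 ± 0.16). Microglia markers were not called (median −0.28, camera BH-adjusted p 0.229), with 1 of 21 genes up and 11 down. Counts adjusted over the list alone were 1 and 12. With ranks the list was called (camera BH-adjusted p = 0.0203). Of these markers, Itgam (−1.10 ± 0.18) and Ptprc (−0.89 ± 0.15) fell and Trem2 (0.97 ± 0.13) rose in the authors' deposited table.

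Stress lists fell under PGC-1α4 as well. Antioxidant defence (median −0.75, camera BH-adjusted p 7.95e-18), ER stress (median −1.08, camera BH-adjusted p 2.55e-22) and p53 targets (median −1.13, camera BH-adjusted p 5.69e-23) fell. Antioxidant defence had 3 up and 20 down of 31 genes, ER stress 2 and 33 of 40, and p53 targets 4 and 25 of 34. With p-values adjusted over the list alone, the counts were 3 and 21, 2 and 34, and 4 and 25. Examples in the authors' deposited table were Slc7a11 (−4.52 ± 0.14), Gsta3 (−3.60 ± 0.20), Nqo1 (−3.20 ± 0.11), Srxn1 (−2.87 ± 0.071), Chac1 (−1.78 ± 0.078) and Plk2 (−3.02 ± 0.07). Heat shock genes (median −1.0, camera BH-adjusted p 9.94e-18) and growth factors (median −0.67, camera BH-adjusted p 2.74e-05) fell. Heat shock genes had 1 up and 17 down of 19 genes, and growth factors 2 and 16 of 27. Identical counts resulted when adjusted over the list alone. Of these, the authors' deposited table gave Hspa1b (−2.22 ± 0.13), Hspb1 (−2.13 ± 0.13), Gdnf (−3.29 ± 0.15) and Bdnf (−1.40 ± 0.069), Hspa1b being uncertain as a near-identical copy of Hspa1a. Pan-reactive genes (median −1.22, camera BH-adjusted p 5.3e-07), A1-type reactive genes (median −0.69, camera BH-adjusted p 0.0035) and A2-type reactive genes (median −0.51, camera BH-adjusted p 5.86e-05) fell. Pan-reactive genes had 1 up and 10 down of 13 genes, A1-type reactive genes 2 and 10 of 13, and A2-type reactive genes 0 and 8 of 12. Nothing in these counts changed when adjusted over the list alone. Gfap was again higher (0.89 ± 0.08 in the authors' deposited table). Extracellular matrix (median −0.43, camera BH-adjusted p 0.0015) and MHC class I (median −0.26, camera BH-adjusted p 0.0469) fell. Extracellular matrix had 3 up and 21 down of 36 genes, and MHC class I 0 and 12 of 22. When adjusted over the list alone, they became 4 and 22, and 0 and 12. Gja1 (−1.96 ± 0.067) and Slc1a2, the main astrocyte glutamate transporter gene (−1.07 ± 0.11), fell in the authors' deposited table. The astrocyte identity list was not called (median 0.01, camera BH-adjusted p 0.837).

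Increases under PGC-1α4 after Ppargc1a included, in the authors' deposited table, Igha (3.02 ± 0.24), Cplx1 (2.80 ± 0.23), Col8a2 (2.57 ± 0.17) and Fndc5 (2.40 ± 0.14). Others in the authors' deposited table were Rapgefl1 (2.38 ± 0.14) and Zfp667 (2.29 ± 0.13). Col8a2, a collagen gene, lies on GRCm38 chromosome 4, 126286793 to 126314330, plus strand. Fatty acid oxidation (median 0.42, camera BH-adjusted p 5.3e-07) and the TCA cycle (median 0.23, camera BH-adjusted p 0.00171) rose. Fatty acid oxidation had 22 up and 3 down of 34 genes, and the TCA cycle 14 and 1 of 22. They came to 23 and 3, and 14 and 1 adjusted over the list alone. Cholesterol synthesis (median 0.23, camera BH-adjusted p 0.0197) and oxidative phosphorylation (median 0.23, camera BH-adjusted p 0.0322) rose. Cholesterol synthesis had 14 up and 0 down of 25 genes, and oxidative phosphorylation 32 and 1 of 76. The counts were 16 and 0, and 31 and 1 adjusted over the list alone. Metabolic genes in the authors' deposited table were Acadvl (1.44 ± 0.075), Slc25a20 (1.34 ± 0.064), Idh3a (1.07 ± 0.056), Ogdh (1.03 ± 0.082), Cox7a1 (1.87 ± 0.19) and Esrra (0.59 ± 0.085). At an inter-gene correlation of 0.05, calls were lost with camera BH-adjusted p = 0.249 for oxidative phosphorylation, 0.107 for cholesterol synthesis and 0.168 for MHC class I. At 0.1 they were lost with camera BH-adjusted p = 0.083 for the TCA cycle, 0.0634 for A1-type reactive genes and 0.132 for extracellular matrix. With fold changes in place of the statistic they were lost with camera BH-adjusted p = 0.0808 for the TCA cycle, 0.112 for MHC class I and 0.112 for cholesterol synthesis. The cell cycle list was not called (median 0.14, camera BH-adjusted p 0.837), with 12 of 40 genes up and 10 down. P-values adjusted over the list alone gave 15 and 11. Signs differed for neuron (median 0.03, mean 0.03, test down), fibroblast (median −0.09, mean −0.04, test up) and endothelial markers (median −0.37, mean −0.13, test up), none of them called.

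**Figure D2:**
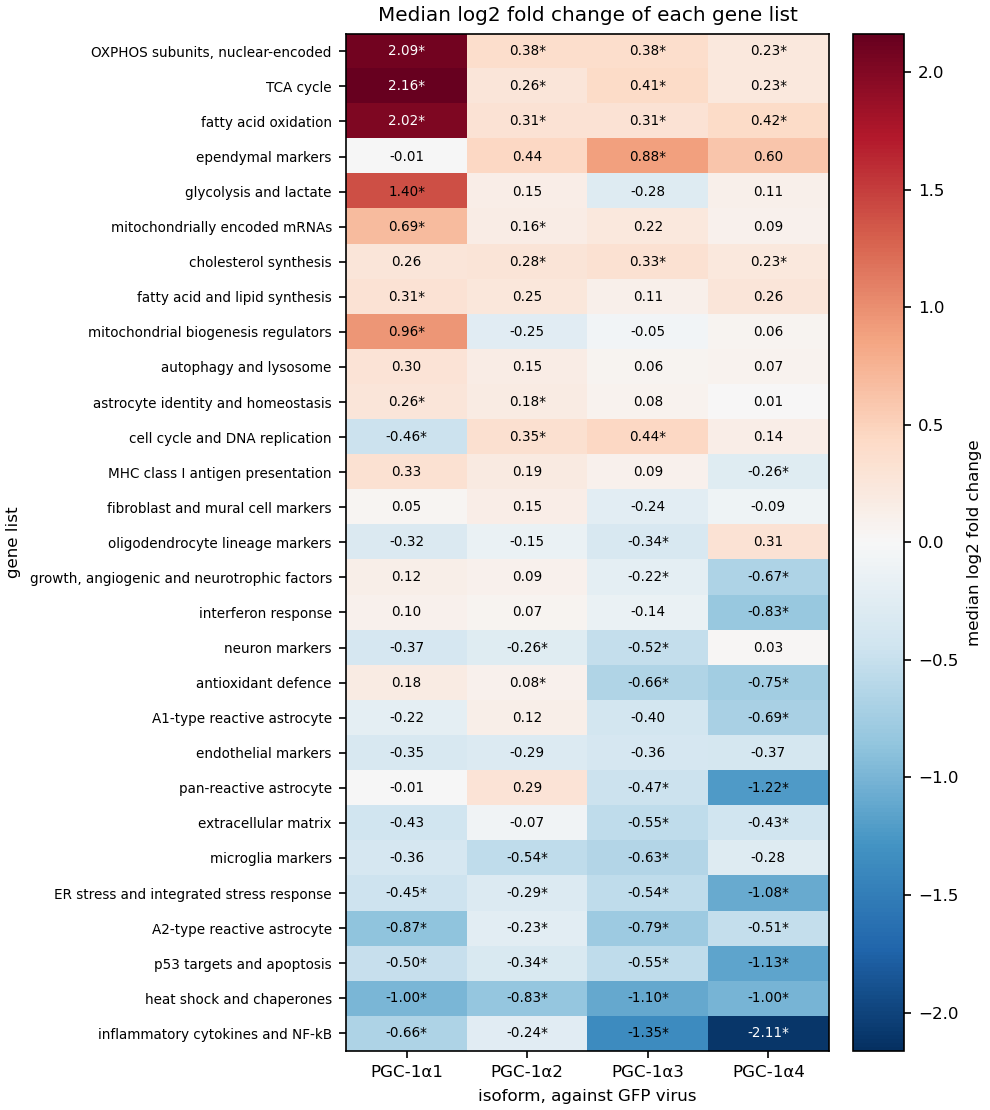
Median log2 fold change of each of the 29 gene lists (y axis) under each isoform against GFP (x axis), coloured from lower (blue) to higher (red). An asterisk marks an adjusted p under 0.05 at an inter-gene correlation of 0.01; oxidative phosphorylation stands at 2.09 under PGC-1α1 and 0.23 under PGC-1α4.

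In the order PGC-1α1 to PGC-1α4, camera called 14, 15, 18 and 16 of the 29 lists with Benjamini-Hochberg adjustment. Autophagy was called under none (medians 0.30, 0.15, 0.06 and 0.07, camera BH-adjusted p 0.125, 0.223, 0.805 and 0.357). With ranks it was called up under PGC-1α1 (camera BH-adjusted p = 0.00504, 20 up and 5 down of 33) and PGC-1α2 (camera BH-adjusted p = 0.0384, 13 up and 4 down of 33). Ependymal markers were not called under PGC-1α2 and PGC-1α4 (camera BH-adjusted p 0.0817 and 0.128), but were called up there by ranks (camera BH-adjusted p = 0.028 and 0.0499) and by fold changes (camera BH-adjusted p = 0.00545 and 0.00753). Fibroblast and mural markers were not called (medians 0.05, 0.15, −0.24 and −0.09, camera BH-adjusted p 0.73, 0.338, 0.32 and 0.678). Endothelial markers were not called either (medians −0.35, −0.29, −0.36 and −0.37, camera BH-adjusted p 0.396, 0.461, 0.805 and 0.837). Gfap rose under all 4 isoforms (0.89, 0.77, 1.15 and 0.89 in the authors' deposited table). Gja1 fell under all 4 (−1.60, −1.06, −1.30 and −1.96 in the authors' deposited table), as did the trophic factor gene Gdnf (−2.49, −1.62, −2.84 and −3.29). Vegfa, an angiogenic factor gene, was higher under PGC-1α1 and lower under the other isoforms (0.71, −0.85, −1.24 and −1.01 in the authors' deposited table).

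**Figure D3:**
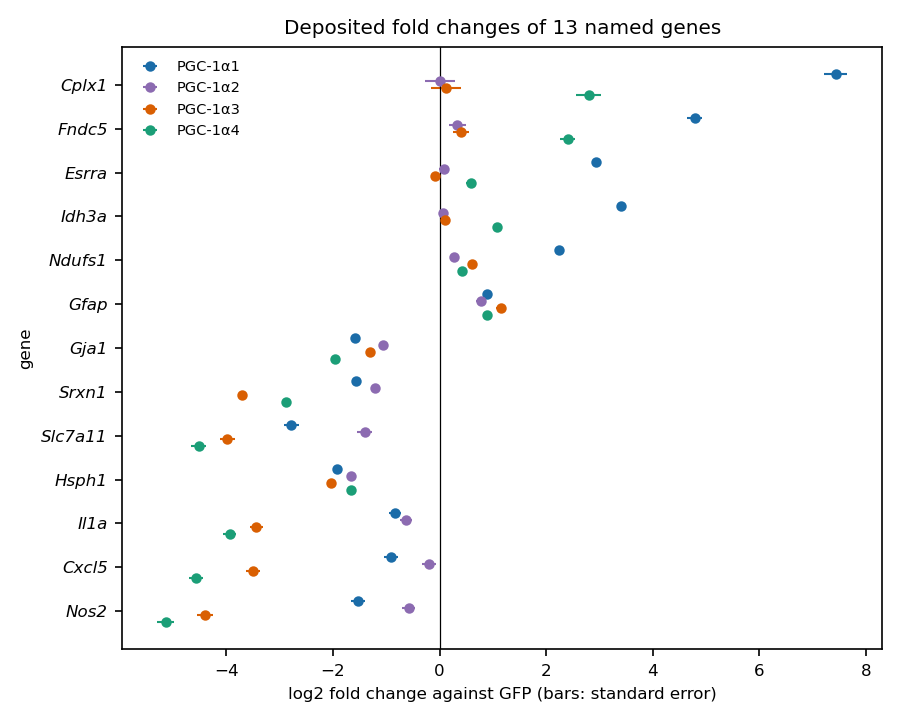
Log2 fold change against GFP (x axis; points, deposited estimates; bars, standard errors) of 13 named genes (y axis) under each isoform. Cplx1 stands at 7.43 under PGC-1α1, and Nos2 at −4.40 under PGC-1α3 and −5.14 under PGC-1α4.

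The isoforms were then compared with each other, from the differences of their deposited fold changes. Between PGC-1α2 and PGC-1α1, energy metabolism was lower under PGC-1α2. Oxidative phosphorylation (median −1.65, camera BH-adjusted p 1.9e-47) and the TCA cycle (median −1.81, camera BH-adjusted p 1.51e-101) were lower. Oxidative phosphorylation had 0 up and 76 down of 76 genes, and the TCA cycle 0 and 22 of 22. The counts adjusted over the list alone were equal. Fatty acid oxidation (median −1.66, camera BH-adjusted p 4.07e-39) and glycolysis (median −1.37, camera BH-adjusted p 7.04e-22) were lower. Fatty acid oxidation had 3 up and 28 down of 34 genes, and glycolysis 1 and 16 of 21. Tests adjusted over the list alone called 3 and 28, and 4 and 16. Biogenesis regulators (median −1.09, camera BH-adjusted p 1.52e-14) and mitochondrially encoded mRNAs (median −0.65, camera BH-adjusted p 8.74e-04) were lower as well. Biogenesis regulators had 1 up and 17 down of 26 genes, and mitochondrially encoded mRNAs 0 and 6 of 13. The result was 2 and 17, and 0 and 7 when adjusted over the list alone. Lower genes, as differences from the authors' deposited table, were Akain1 (−7.98 ± 0.57), Atp2b2 (−7.89 ± 0.32) and Cplx1 (−7.42 ± 0.36). Higher ones, as differences from the authors' deposited table, were Nqo1 (2.09 ± 0.14), Nyx (1.84 ± 0.23), Cdh4 (1.84 ± 0.24) and Ptgr1 (1.71 ± 0.16). The cell cycle (median 0.71, camera BH-adjusted p 9.15e-09), inflammatory genes (median 0.37, camera BH-adjusted p 8.74e-04) and A2-type reactive genes (median 0.50, camera BH-adjusted p 0.0101) were higher under PGC-1α2. The cell cycle had 33 up and 2 down of 40 genes, inflammatory genes 18 and 0 of 34, and A2-type reactive genes 8 and 1 of 11. Identical counts resulted when adjusted over the list alone. In all, 6686 of 17831 genes differed (3087 higher and 3599 lower under PGC-1α2), 1646 of them by at least 1 on the log2 scale. Calls for higher p53 targets (median 0.21, camera BH-adjusted p 0.0239) and lower growth factors (median −0.02, camera BH-adjusted p 0.0331) were lost at a correlation of 0.05 (camera BH-adjusted p = 0.17 for both). Growth factors had 2 up and 11 down of 27 genes and a mean of −0.39, and their call was lost with ranks (camera BH-adjusted p = 0.248) and fold changes (0.062), as was that of p53 targets with fold changes (0.104). At 0.1, camera BH-adjusted p = 0.132 for inflammatory genes and 0.103 for A2-type reactive genes.

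Between PGC-1α3 and PGC-1α1, the energy lists were lower under PGC-1α3. Oxidative phosphorylation (median −1.66, camera BH-adjusted p 6.67e-39) and the TCA cycle (median −1.81, camera BH-adjusted p 1.13e-79) were lower. Oxidative phosphorylation had 0 up and 76 down of 76 genes, and the TCA cycle 0 and 21 of 22. Adjusted over the list alone, they were 0 and 76, and 0 and 22. Fatty acid oxidation (median −1.62, camera BH-adjusted p 1.66e-31) and glycolysis (median −1.33, camera BH-adjusted p 2.74e-27) were lower. Fatty acid oxidation had 1 up and 28 down of 34 genes, and glycolysis 0 and 16 of 21. Nothing in these counts changed when adjusted over the list alone. Under PGC-1α3, antioxidant defence (median −0.93, camera BH-adjusted p 3.37e-10) was lower, and the cell cycle (median 0.83, camera BH-adjusted p 7.82e-11) higher. Antioxidant defence had 0 up and 28 down of 31 genes, and the cell cycle 29 and 2 of 40. These were 0 and 28, and 31 and 2 when adjusted over the list alone. Higher genes, as differences from the authors' deposited table, were Gpr25 (3.35 ± 0.18), Glrp1 (3.20 ± 0.20), H4c12 (3.15 ± 0.24) and Hepacam2 (3.07 ± 0.29), H4c12 being uncertain. Lower ones, as differences from the authors' deposited table, were Akain1 (−7.92 ± 0.57), St8sia5 (−7.48 ± 0.37) and Cplx1 (−7.31 ± 0.35). Biogenesis regulators (median −0.84, camera BH-adjusted p 2.11e-09), growth factors (median −0.35, camera BH-adjusted p 2.46e-04) and mitochondrially encoded mRNAs (median −0.79, camera BH-adjusted p 0.00228) were lower. Biogenesis regulators had 3 up and 17 down of 26 genes, growth factors 1 and 14 of 27, and mitochondrially encoded mRNAs 0 and 9 of 13. Counts adjusted over the list alone were 3 and 18, 2 and 14, and 0 and 9. In all, 8053 genes differed (3666 higher, 4387 lower), 2363 of them by at least 1 on the log2 scale. The call of lower inflammatory genes (median −0.70, camera BH-adjusted p 0.00918) was lost at a correlation of 0.05 (camera BH-adjusted p = 0.101). For neuron markers (median −0.07, camera BH-adjusted p 0.00763) the test pointed down, with 4 up and 7 down of 19 genes and a mean of −0.75. That call was lost with ranks (camera BH-adjusted p = 0.43) and at a correlation of 0.05 (camera BH-adjusted p = 0.0514). At 0.1, camera BH-adjusted p = 0.0592 for growth factors and 0.0568 for mitochondrially encoded mRNAs.

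Between PGC-1α4 and PGC-1α1, the same energy lists were lower under PGC-1α4, namely oxidative phosphorylation (median −1.85, camera BH-adjusted p 7.03e-46) and the TCA cycle (median −1.83, camera BH-adjusted p 2.36e-77). Also lower were fatty acid oxidation (median −1.31, camera BH-adjusted p 2.07e-22) and glycolysis (median −1.32, camera BH-adjusted p 7.81e-20). Inflammatory genes (median −1.33, camera BH-adjusted p 2.1e-12) and the interferon response (median −1.01, camera BH-adjusted p 9.84e-08) were lower. Inflammatory genes had 2 up and 28 down of 34 genes, and the interferon response 1 and 38 of 42. With p-values adjusted over the list alone, the counts were 2 and 29, and 1 and 38. Growth factors (median −0.95, camera BH-adjusted p 5e-08) and antioxidant defence (median −0.87, camera BH-adjusted p 1.23e-08) were lower. Growth factors had 0 up and 19 down of 27 genes, and antioxidant defence 0 and 25 of 31. The counts adjusted over the list alone were equal. Lower genes, as differences from the authors' deposited table, were Akain1 (−7.76 ± 0.56), H2-Eb1 (−6.11 ± 0.34), Tesc (−5.81 ± 0.30) and St8sia5 (−5.43 ± 0.32). Higher ones, as differences from the authors' deposited table, were Igha (5.28 ± 0.41), Col8a2 (2.7 ± 0.26), Rhof (2.59 ± 0.21) and Egr1 (2.56 ± 0.12). In all, 9186 genes differed (4246 higher, 4940 lower), 2715 of them by at least 1 on the log2 scale. Further lists were lower, with biogenesis regulators (median −0.74, camera BH-adjusted p 9.84e-08), mitochondrially encoded mRNAs (median −0.60, camera BH-adjusted p 7.78e-05) and pan-reactive genes (median −0.84, camera BH-adjusted p 0.00202). Lower too were astrocyte identity (median −0.37, camera BH-adjusted p 0.00247), ER stress (median −0.62, camera BH-adjusted p 2.32e-04) and MHC class I (median −0.64, camera BH-adjusted p 0.00406), and higher was the cell cycle (median 0.58, camera BH-adjusted p 0.0012). Calls for p53 targets (median −0.30) and oligodendrocyte markers (median 0.49) were lost at a correlation of 0.05, with camera BH-adjusted p = 0.185 and 0.0621, the former also with fold changes (0.173). At 0.1, camera BH-adjusted p = 0.149 for astrocyte identity, 0.0884 for ER stress, 0.122 for MHC class I and 0.132 for the cell cycle.

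PGC-1α3 and PGC-1α2 differed in the fewest genes of the 6 pairs. Antioxidant defence (median −0.73, camera BH-adjusted p 5.96e-35), inflammatory genes (median −1.04, camera BH-adjusted p 9.84e-33) and pan-reactive genes (median −0.75, camera BH-adjusted p 3.51e-09) were lower under PGC-1α3. Antioxidant defence had 1 up and 19 down of 31 genes, inflammatory genes 4 and 26 of 34, and pan-reactive genes 1 and 8 of 13. When adjusted over the list alone, they became 1 and 21, 6 and 26, and 1 and 8. Lower genes, as differences from the authors' deposited table, were Nos2 (−3.82 ± 0.19), Nqo1 (−3.31 ± 0.15), Cxcl5 (−3.29 ± 0.19) and Ptgr1 (−2.91 ± 0.16). Higher ones, as differences from the authors' deposited table, were Glrp1 (3.5 ± 0.20), Gpr25 (3.25 ± 0.18), Hepacam2 (3.15 ± 0.29) and H4c11 (3.10 ± 0.21), H4c11 being uncertain. Extracellular matrix (median −0.43, camera BH-adjusted p 2.92e-07), heat shock genes (median −0.27, camera BH-adjusted p 1.96e-05) and A2-type reactive genes (median −0.68, camera BH-adjusted p 2.66e-04) were lower too. Extracellular matrix had 0 up and 16 down of 36 genes, heat shock genes 1 and 9 of 19, and A2-type reactive genes 1 and 7 of 11. They came to 0 and 17, 1 and 9, and 1 and 9 adjusted over the list alone. Oxidative phosphorylation was not called (median 0.01, camera BH-adjusted p 0.549). In all, 3801 genes differed (1705 higher, 2096 lower), 703 of them by at least 1 on the log2 scale. The count was 6780 when the covariance from the shared GFP libraries was rebuilt. The call for glycolysis (median −0.27, camera BH-adjusted p 0.00196) was lost at a correlation of 0.1 (camera BH-adjusted p = 0.112). At 0.05, calls were lost with camera BH-adjusted p = 0.0599 each for lower p53 targets, growth factors and oligodendrocyte markers. Further ones had camera BH-adjusted p = 0.0531 for lower A1-type reactive genes, 0.226 for lower ER stress and 0.188 for higher biogenesis regulators. With fold changes in place of the statistic, calls were lost with camera BH-adjusted p = 0.148 for biogenesis regulators, 0.184 for ER stress, 0.196 for p53 targets and 0.184 for glycolysis. After the GC and length correction it was 0.0858 for biogenesis regulators and 0.124 for ER stress.

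Between PGC-1α4 and PGC-1α2, inflammatory and interferon genes were lower under PGC-1α4. Inflammatory genes (median −1.72, camera BH-adjusted p 9.41e-54) and the interferon response (median −0.84, camera BH-adjusted p 2.87e-17) were lower. Inflammatory genes had 1 up and 29 down of 34 genes, and the interferon response 2 and 37 of 42. The counts were 1 and 30, and 2 and 38 adjusted over the list alone. Antioxidant defence (median −0.69, camera BH-adjusted p 1.21e-17) and pan-reactive genes (median −0.79, camera BH-adjusted p 2.21e-13) were lower. Antioxidant defence had 1 up and 23 down of 31 genes, and pan-reactive genes 0 and 10 of 13. P-values adjusted over the list alone gave 2 and 26, and 0 and 12. ER stress (median −0.55, camera BH-adjusted p 1.54e-12) and p53 targets (median −0.54, camera BH-adjusted p 2.44e-11) were lower as well. ER stress had 3 up and 28 down of 40 genes, and p53 targets 3 and 22 of 34. Tests adjusted over the list alone called 3 and 29, and 4 and 23. Growth factors (median −0.76, camera BH-adjusted p 2.71e-06) and A1-type reactive genes (median −0.73, camera BH-adjusted p 9.22e-06) were lower as well. Growth factors had 2 up and 15 down of 27 genes, and A1-type reactive genes 2 and 9 of 13. The result was 2 and 16, and 2 and 10 when adjusted over the list alone. Lower genes, as differences from the authors' deposited table, were Nos2 (−4.56 ± 0.20), Cxcl5 (−4.36 ± 0.19), Nyx (−3.66 ± 0.25) and Il1b (−3.60 ± 0.24). Higher ones, as differences from the authors' deposited table, were Igha (3.99 ± 0.37), Rapgefl1 (2.26 ± 0.21) and Col8a2 (2.25 ± 0.26). In all, 6514 genes differed (3398 higher, 3116 lower), 1238 of them by at least 1 on the log2 scale. Lower lists also included MHC class I (median −0.43, camera BH-adjusted p 2.79e-04), A2-type reactive genes (median −0.24, camera BH-adjusted p 0.00117) and extracellular matrix (median −0.28, camera BH-adjusted p 4.12e-04), the last with camera BH-adjusted p = 0.0977 at a correlation of 0.1. Higher lists lost at 0.05 had camera BH-adjusted p = 0.0532 for fatty acid oxidation and 0.116 for biogenesis regulators. Calls for the cell cycle (median −0.26) and oligodendrocyte markers (median 0.60) were lost there too, with camera BH-adjusted p = 0.0879 and 0.13. With fold changes, calls were lost with camera BH-adjusted p = 0.147 for fatty acid oxidation, 0.113 for biogenesis regulators and 0.139 for the cell cycle, and after the GC and length correction with 0.0597 for biogenesis regulators.

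Between PGC-1α4 and PGC-1α3, the genes furthest below under PGC-1α4, as differences from the authors' deposited table, included Glrp1 (−5.01 ± 0.21), Gpr25 (−4.45 ± 0.19), Insrr (−4.39 ± 0.17) and Enpep (−4.23 ± 0.19). Against GFP, the authors' deposited table gave −0.97, −0.87, 2.38 and −2.07 for Gpr25, a G protein-coupled receptor gene, in the order PGC-1α1 to PGC-1α4. Gpr25 lies on GRCm38 chromosome 1, 136259797 to 136260873, minus strand. For Insrr, an insulin receptor-related gene, the authors' deposited table gave −0.60, −0.59, 2.32 and −2.07 in that order. Higher under PGC-1α4, as differences from the authors' deposited table, were Igha (3.65 ± 0.37), Hspa1a (2.55 ± 0.20) and Hspa1b (2.43 ± 0.18), the Hspa1 pair being uncertain. The interferon response (median −0.69, camera BH-adjusted p 5.26e-13) and inflammatory genes (median −0.61, camera BH-adjusted p 1.01e-10) were lower under PGC-1α4. The interferon response had 2 up and 31 down of 42 genes, and inflammatory genes 3 and 23 of 34. Adjusted over the list alone, they were 2 and 37, and 4 and 23. ER stress (median −0.41, camera BH-adjusted p 5.26e-08), the cell cycle (median −0.40, camera BH-adjusted p 6.32e-06) and p53 targets (median −0.35, camera BH-adjusted p 1.44e-05) were lower too. ER stress had 4 up and 25 down of 40 genes, the cell cycle 0 and 21 of 40, and p53 targets 5 and 19 of 34. These were 4 and 25, 1 and 22, and 5 and 20 when adjusted over the list alone. Oligodendrocyte markers (median 0.71, camera BH-adjusted p 1.44e-05), neuron markers (median 0.35, camera BH-adjusted p 0.00569) and heat shock genes (median 0.24, camera BH-adjusted p 0.00163) were higher. Oligodendrocyte markers had 13 up and 0 down of 18 genes, neuron markers 8 and 0 of 19, and heat shock genes 9 and 3 of 19. Counts adjusted over the list alone were 17 and 0, 8 and 0, and 10 and 5. In all, 6234 genes differed (3257 higher, 2977 lower), 1126 of them by at least 1 on the log2 scale. The list of pan-reactive genes (median −0.30, camera BH-adjusted p 0.00786) was lower. At a correlation of 0.1, calls were lost with camera BH-adjusted p = 0.117 for pan-reactive genes, 0.129 for neuron markers and 0.0884 for heat shock genes. Lower lists lost at 0.05 had camera BH-adjusted p = 0.0605 for MHC class I, 0.0727 for A1-type reactive genes and 0.104 for growth factors. Higher ones had camera BH-adjusted p = 0.135 for fatty acid oxidation and 0.154 for glycolysis. With ranks, calls were lost with camera BH-adjusted p = 0.126 for glycolysis, 0.0923 for heat shock genes and 0.0755 for growth factors, and with fold changes with camera BH-adjusted p = 0.285 for fatty acid oxidation, 0.422 for glycolysis and 0.0866 for growth factors. The glycolysis call was also lost after the GC and length correction (camera BH-adjusted p = 0.136).

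Across the 17831 genes tested in all comparisons with GFP, 1739 were called up and 1727 down under all 4 isoforms, and 2544 were called up under some isoform and down under another. Heat shock genes had medians of −1.0, −0.83, −1.10 and −1.0. Over 14203 genes, fold changes correlated most between PGC-1α2 and PGC-1α3 (Pearson r 0.753, Spearman rho 0.766, covariance 0.189). They correlated least between PGC-1α1 and PGC-1α4 (Pearson r 0.50, rho 0.498 and covariance 0.284). The other pairs gave Pearson r of 0.591 for PGC-1α1 and PGC-1α2, 0.504 for PGC-1α1 and PGC-1α3, 0.578 for PGC-1α2 and PGC-1α4 and 0.681 for PGC-1α3 and PGC-1α4. Their rho values were 0.650, 0.558, 0.560 and 0.640, and their covariances 0.195, 0.273, 0.152 and 0.294. With no effect at all, the shared GFP libraries gave simulated r from 0.498 to 0.502 and covariances from 0.0081 to 0.0082. These 6 correlations are across genes, which are not independent replicates, so no p is given. PGC-1α2 and PGC-1α3 shared 3158 up and 2850 down calls (1177 and 1044 if independent), with 194 opposite. PGC-1α3 and PGC-1α4 shared 3193 up and 3322 down (1454 and 1311 if independent), with 758 opposite. PGC-1α1 and PGC-1α4 shared 3032 up and 2964 down (1548 and 1471), with 1384 opposite. With no effect, the simulation gave 0 shared calls, but it calls few genes, so this is no benchmark. The 3 GFP libraries could not be split, so part of the excess may come from them.

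**Figure D4:**
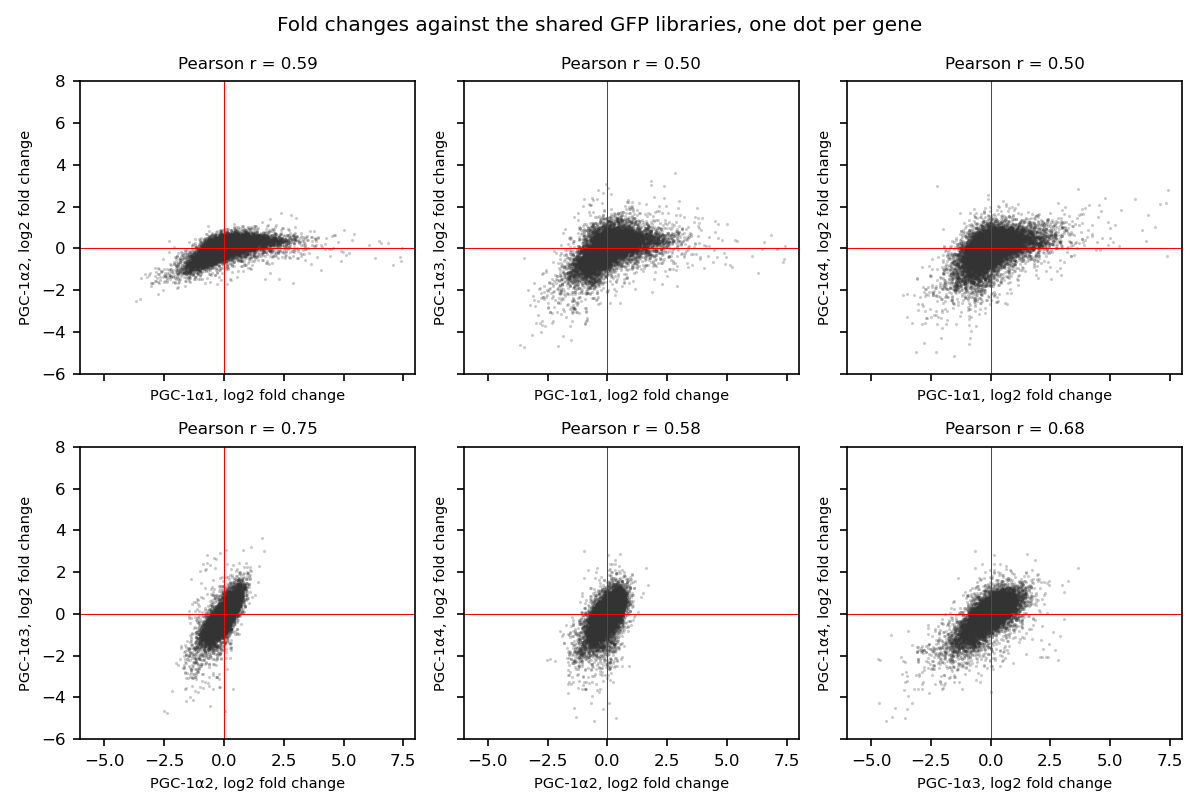
Log2 fold changes against GFP of each pair of isoforms (x and y axes), with a dot per gene of base mean 50 or more, Ppargc1a left out. The cloud is narrowest for PGC-1α2 and PGC-1α3 (r 0.75), and all pairs share the GFP libraries, which alone gave a simulated r near 0.50. The simulated covariances were far smaller than those seen, with 0.0082 against 0.152 for PGC-1α2 and PGC-1α4, the pair with the lowest covariance.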

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

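All alternatives here were chosen after the data were seen, except the correlations restricted to genes called in at least one contrast, which were planned. Counts of called genes against GFP stayed within 1.5 times under Benjamini-Hochberg adjustment over all genes, an adjusted p under 0.01, a base mean of at least 10 and median centring, for all 4 isoforms. Counts between isoforms did too, except PGC-1α3 against PGC-1α2, where rebuilding the shared GFP covariance gave 6780 genes in place of 3801. That alternative removes error counted more than once, by its construction. At an inter-gene correlation of 0.1, fewer lists were called, as the preset value widens every list's error. Against GFP there were 10 under PGC-1α1, 3 under PGC-1α2, 6 under PGC-1α3 and 10 under PGC-1α4. Between isoforms there were 7 for PGC-1α2 and 7 for PGC-1α3 against PGC-1α1, 11 for PGC-1α4 against PGC-1α1, 6 for PGC-1α3 against PGC-1α2 and 6 for PGC-1α4 against PGC-1α3. At 0.05, 7 lists were called for PGC-1α3 against PGC-1α2 and 9 for PGC-1α4 against PGC-1α3. Over genes called in at least one contrast, Pearson r was 0.604 for PGC-1α1 and PGC-1α2, 0.772 for PGC-1α2 and PGC-1α3 and 0.595 for PGC-1α2 and PGC-1α4, and the cause was not tested. Of 144 called lists, calls were lost for 34 at a correlation of 0.05, 68 at 0.1, 22 with fold changes in place of the statistic, 11 with ranks and 6 after the GC and length correction. Of 146 lists not called, 24 were called with ranks, 9 with fold changes and 4 after that correction. Of the named genes' calls, 30 were lost after that correction and 4 after median centring. None of these called lists reversed the direction of its test, and none of the named genes' calls reversed. The medians of called lists did change sign after the GC and length correction for antioxidant defence under PGC-1α2 (0.08 to −0.06) and for growth factors between PGC-1α2 and PGC-1α1 (−0.02 to 0.0031), as did medians of some lists that were not called. The cause was not tested.

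No paired analysis was possible because the count columns carry no sample labels and the deposited comparisons carry no replicate numbers. For the same reason the planned fits with other normalizations, filters, tests, prior counts and sample subsets, the removal of Ppargc1a from library sizes, leaving out each replicate, the estimated inter-gene correlation, fry and other splits of the samples were not run. Whether a single library decides any value is therefore unknown here. Genes without an adjusted p, all with low base means, were not tested, and depth per library is not given.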

Other observations

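The gene families here and all tests of explanations were chosen after the data were seen. Only the prediction on RNA without poly(A) tails is recorded as written before its own test. Intervals of list medians come from resampling the list's genes, which are not independent replicates, so they do not measure spread between libraries. Beyond the fixed lists, families of the mitochondrion rose with the oxidative phosphorylation genes under PGC-1α1, by camera with Benjamini-Hochberg (BH) adjustment. They were the mitochondrial ribosome (76 up and 0 down, median 1.08, camera BH-adjusted p 3.5e-20, of 78) and protein import (23 up and 2 down, median 1.31, camera BH-adjusted p 3.15e-09, of 25). SLC25 carriers (28 up and 7 down, median 0.51, camera BH-adjusted p 1.44e-09, of 45) and coenzyme Q synthesis (11 up and 0 down, median 0.75, camera BH-adjusted p 1.96e-07, of 11) also rose. The mitochondrial ribosome also rose under PGC-1α2 (50 up and 1 down, median 0.33, camera BH-adjusted p 1.65e-05) and PGC-1α3 (52 up and 2 down, median 0.39, camera BH-adjusted p 6.73e-05) and was not called under PGC-1α4 (22 up and 4 down, median 0.13, camera BH-adjusted p 0.153). Coenzyme Q synthesis rose under PGC-1α2 (9 up and 1 down, median 0.35, camera BH-adjusted p 0.0105), PGC-1α3 (7 up and 2 down, median 0.48, camera BH-adjusted p 0.0107) and PGC-1α4 (8 up and 0 down, median 0.33, camera BH-adjusted p 0.0296) as well. Protein import rose under PGC-1α2 (15 up and 3 down, median 0.30, camera BH-adjusted p 0.0294) and SLC25 carriers under PGC-1α4 (22 up and 11 down, median 0.25, camera BH-adjusted p 0.0419). Protein import was not called under PGC-1α3 (camera BH-adjusted p 0.05003) or PGC-1α4 (0.764), nor SLC25 carriers under PGC-1α2 (0.093) or PGC-1α3 (0.452). Peroxins, which build peroxisomes, rose under PGC-1α1 (15 up and 1 down, median 0.42, camera BH-adjusted p 0.00873, of 17), PGC-1α2 (10 up and 1 down, median 0.27, camera BH-adjusted p 0.0294) and PGC-1α4 (13 up and 1 down, median 0.40, camera BH-adjusted p 0.00102). They were not called under PGC-1α3 (9 up and 1 down, median 0.23, camera BH-adjusted p 0.0924). At an inter-gene correlation of 0.05, camera BH-adjusted p was 0.0751 for coenzyme Q synthesis and 0.195 for SLC25 carriers under PGC-1α4, which ended these calls. It was 0.161 for protein import and 0.144 for peroxins under PGC-1α2, which ended these as well. After the GC and length correction, camera BH-adjusted p was 0.0526 for coenzyme Q synthesis and 0.0741 for SLC25 carriers under PGC-1α4, and 0.172 for protein import under PGC-1α2.

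Genes of the cytosolic ribosome (82 members) fell under PGC-1α3 (0 up and 62 down, median −0.51, camera BH-adjusted p 1.37e-04) and PGC-1α4 (0 up and 69 down, median −0.56, camera BH-adjusted p 4.61e-05). They were not called under PGC-1α1 (14 up and 7 down, median 0.04, camera BH-adjusted p 0.828) or PGC-1α2 (1 up and 0 down, median 0.00, camera BH-adjusted p 0.813), and the isoforms were not tested against each other for this family. Proteasome subunits (38 members) fell under PGC-1α3 (2 up and 19 down, median −0.29, camera BH-adjusted p 0.00756) and PGC-1α4 (1 up and 29 down, median −0.35, camera BH-adjusted p 0.00101), as did glutathione transferases (24 members; 3 up and 13 down, median −0.55, camera BH-adjusted p 0.00413 and 5 up and 13 down, median −0.59, camera BH-adjusted p 0.0173). At an inter-gene correlation of 0.05, the camera BH-adjusted p was 0.0706 for proteasome subunits under PGC-1α3 and 0.0751 for glutathione transferases under PGC-1α4. Under PGC-1α1 and PGC-1α2 neither family was called, with camera BH-adjusted p 0.851 and 0.236 for proteasome subunits and 0.805 and 0.236 for glutathione transferases. After the GC and length correction, proteasome subunits were called under PGC-1α2 (camera BH-adjusted p 0.0479).

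Replication-dependent histone genes (54 members, near-identical copies that make single values uncertain) were higher under PGC-1α3 (31 up and 0 down, median 0.70, camera BH-adjusted p 4.79e-05) and lower under PGC-1α4 (0 up and 38 down, median −0.90, camera BH-adjusted p 4.61e-05). Fewer cycling cells under PGC-1α4 are argued against by the cell cycle list, whose median there was 0.142 (95% interval −0.0212 to 0.265) against −0.899 (−1.22 to −0.712) for the histones, and GC content and length by corrected medians of 0.771 and −0.771. More cycling cells under PGC-1α3 remain open, with a cell cycle median of 0.441 (0.332 to 0.607), although under PGC-1α2 that list had a median of 0.355 (0.218 to 0.453) and the histones −0.32 (camera BH-adjusted p 0.0294, a call lost at an inter-gene correlation of 0.05 with camera BH-adjusted p = 0.171). For uneven capture of RNA without poly(A) tails, which could not be settled, 5 small RNA genes in the authors' deposited table had a median of −0.281 under PGC-1α4, with Rmrp (−1.01) and Rpph1 (−0.81) called down like the histones, and of −0.576 under PGC-1α3, with Rmrp (−4.19), Rpph1 (−3.45) and Gm25184 (−0.58) called against the histones and Gm27343 (1.09) with them. A difference in the isoforms' action may also be the cause and stays untested.

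The inflammatory list was lowest under PGC-1α4, with a median of −2.11 (95% interval −2.64 to −1.49), and was lower there than under each other isoform. Loss of microglia as the whole cause is argued against by the median of the 21 microglia markers, −0.283 (−0.560 to −0.128), above the inflammatory median by 1.82 (permutation p 6e-05, two-sided, between genes of the lists, which share 0 genes). Genes of a list are not independent replicates, so this permutation p does not measure spread between libraries. How far astrocytes express the microglia markers was not measured. GC content and length are argued against by a corrected inflammatory median of −2.21. With values per library unused and no uninfected group, an isoform effect may explain the pattern only as a hypothesis.

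PGC-1α2 had the highest Ppargc1a counts (15.4% of summed normalized counts) and the fewest called genes (7731). Among 12834 genes called under PGC-1α1 or PGC-1α2, 21.6% had the larger absolute change under PGC-1α2, but this restates the fewer calls. Each isoform came with its own Ppargc1a count, and counts also depend on transcript length. Whether the amount of mRNA sets the response therefore stays open. The median standard errors had a ratio of 0.998 (PGC-1α2 over PGC-1α1). Dispersions were nearly the same in all comparisons, as in a single fit over all groups. This ratio therefore cannot show whether the PGC-1α2 libraries were noisier, and lower precision stays open. Differences in the isoforms' sequences may underlie the pattern, but protein levels were not measured and this stays a hypothesis.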
